A study of Oncorhynchus kisutch with 226 samples.

How the data were processed

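Liver RNA of juvenile coho salmon (Oncorhynchus kisutch, a Pacific salmon that hatches and grows in rivers and then migrates to sea) was measured on 2-colour microarrays, with 1 fish per array. Per the labels' protocols, total RNA was extracted with a magnetic-bead kit and amplified, every fish's RNA was coupled to the same Alexa dye, and a pool of all liver samples was coupled to another Alexa dye as the common reference. No dye swap is named in the labels. Scanner, image quantification, background correction, normalization and the rule by which cells were left empty are not given in the sources used here.

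The values used were the log2 ratios deposited by the authors, 1 per probe and array, of each fish against the pooled reference. The base of the logarithm and the numerator of the ratio were not stated and were taken from the values. A base of 10 was excluded by the range of the deposited values, from -10.13 to 10.00. A pool of all samples lies above the mean of their logarithms by an amount that grows with the variance, so the mean of sample over reference falls with a probe's variance, with a slope near -0.347 for a base of 2. The observed slope of probe mean on probe variance was -0.364 (Spearman rho = -0.473 across probes). In a check added after the data were examined, over 9086 probes measured on between 30% and 90% of arrays, the stage in which a probe was measured on more arrays also tended to have its higher ratio (Spearman rho = 0.497 for smolt against summer, 0.277 for summer against fall and 0.527 for smolt against fall, across probes, which are not independent replicates). The direction, fish over reference, is therefore likely and not stated by the submitters. With the opposite numerator every "higher" would read "lower" and the counts would stay as they are. Individual arrays correlated down to r = -0.46, and 427 of 25420 pairs of arrays lay below -0.3. All fish carried the same dye per the labels, and fish of different stages can lie on opposite sides of the pool, so the direction was kept for all arrays.

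The table held 43567 probes, of which 5 were never measured, and 49.9% of its cells were empty. Between 12760 and 30826 probes were measured per array. Medians of the arrays lay between -0.01 and 0.06 on the log2 scale. The number of arrays limits the precision. Probes measured on at least 80% of arrays were kept, which left 16802, and 7169 of these were measured on every array. Probe identifiers gave the column and row of the spot. They were not paired with gene names in the sources used here, and the gene-name table at hand did not list them, so no gene is named, and the gene list tests and the test of a growth factor gene planned before the data were examined were not run.

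Stages were taken from the season label, and every label set also gave year, origin (hatchery or wild), sex, catch area, fork length and slide. All titles carry the word smolt, also for parr and ocean fish, and were not used for grouping. Body mass was entered as 0 for 23 fish and was treated as missing. Each array was a separate fish. No column of the table was left without a sample.

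The ratios were fitted per probe with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3). The 6 stages entered 1 fit with 5 successive contrasts and the contrast of the mean of the 4 ocean stages against the mean of parr and smolt, with stages weighted equally. The slide was a random block, with a consensus correlation of 0.186 estimated by duplicateCorrelation on 3000 randomly drawn probes. Of 60 slides, 32 held more than 1 stage. Origin was tested within Capilano smolts and within Strait of Georgia fish of 2009 per season, catch area within wild fish of 2009 per season, and catch year within wild fall fish of the Strait. Sex (with season as a covariate) and fork length (per season) were tested over all summer and fall fish, so origin, area and year were mixed there. The same slide correlation was used, and differences of effects between fall and summer were tested as interaction terms. A probe was called at a Benjamini-Hochberg adjusted p below 0.05 over all probes tested. Because probes were unnamed, the rule fixed before the data were examined allowed at most 2 probe identifiers per direction and comparison, and the 2 largest changes among called probes were taken. A value of ± gives the SD between fish.

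The fits were tested on simulated ratios with the real probe means, spreads and empty cells and a correlation within slides, with 200 changed probes per comparison among 16802. At a change of 1 (log2), 39.4% of 66 changed probes were recovered for smolt versus parr, 81.8% for ocean spring versus smolt, 80.3% for ocean summer versus ocean spring, 100% for ocean fall versus ocean summer, 74.2% for ocean winter versus ocean fall and 7.58% for hatchery versus wild Capilano smolts. At a change of 0.5, 73.1% of 67 were recovered for ocean fall versus ocean summer and 1.49% for smolt versus parr. Called unchanged probes numbered between 0 and 6 per comparison. Simulated noise was independent between probes, which real probes are not. Recovery at an adjusted p also depends on how many probes change. Between the real Capilano origins 8297 probes were called, so the 7.58% does not describe that comparison, and each real stage comparison called more than 200.

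Alternatives covered the slide term, quantile normalization, centring, the probe filter, the variance model, equal group sizes, catch year, origin and matched subsets of fish. Alternatives added after the data were examined were the score on the leading axis of variation within summer and fall fish, the number of measured probes, the slide as a fixed block for the comparisons within stages, sex-specific fits for winter, and fits without fish that stood apart. The leading axis was the first principal component of the 7169 probes measured on every array, over the 138 summer and fall fish after removal of each stage's mean. It held 36% of their variance, and every fish was scored on it in units of the SD of those 138 fish. The score is computed from the same ratios, so with it as a covariate a lost call does not show the source of a difference. Figures were drawn with matplotlib 3.10.9.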

Results

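Liver expression was measured in coho salmon of 6 life stages. Freshwater fish comprised 8 parr, the stage before seaward migration, and 54 smolts, the migrating stage. Ocean fish comprised 14 caught in spring, 67 in summer, 71 in fall and 12 in winter. Fish came from 2 years, and the parr were all hatchery fish of the Chilliwack River from 2008. Fork length, the length from snout to tail fork, rose from 5.10 ± 0.262 cm in parr to 11.2 ± 1.38 cm in smolts, 11.3 ± 1.07 cm in spring, 17.9 ± 2.18 cm in summer, 25.3 ± 3.05 cm in fall and 34.7 ± 2.13 cm in winter. Each ratio below is the log2 ratio of a fish to a pool of all liver samples, with its likely direction as described for the processing. Winter arrays had 25538 ± 4003 measured probes, and the means of the other stages lay between 21023 and 22014. The median correlation between arrays of the same stage was 0.522 on the same slide and 0.214 on different slides. Across stages it was 0.166 on the same slide and 0.117 on different slides.

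Parr and smolts were compared for the change that precedes migration. Probe C085R057 rose from -4.66 ± 1.62 in 8 parr to -0.94 ± 0.88 in 54 smolts, a 13.6-fold difference (log2 change 3.76, SE 0.44, adjusted p = 4.63e-12), and C253R126 rose by 3.50 (adjusted p = 1.01e-05). C038R110 stood at 4.18 ± 1.25 in parr and 0.14 ± 1.82 in 53 smolts, a change of -4.10 (SE 0.62, adjusted p = 2.09e-07), and 52 of the 53 smolts lay below every parr. C077R080 changed by -4.03 (SE 0.45, adjusted p = 6.52e-13). In all, 864 probes were higher and 903 lower in smolts of 16801 tested with limma, and 916 of them changed by at least 1 on the log2 scale. Parr shared no slide with any other stage, so slide and stage cannot be told apart for them. With the 8 smolts of the Chilliwack River from 2008, which were wild, 621 probes were called, and with quantile normalization 855.

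For the step from river to sea, smolts were compared with ocean spring fish, which were other fish of partly other stocks. By the stock label most spring fish were of ECVI, a stock that among smolts held only Puntledge hatchery fish. No spring fish was of the Capilano smolts' stock, so stock and stage were partly mixed. C105R058 rose from -2.65 ± 0.80 in 51 smolts to 0.80 ± 1.27 in 14 spring fish (log2 change 3.45, SE 0.34, adjusted p = 5.01e-16), with 12 of the 14 above every smolt. C195R090 rose by 3.22 (SE 0.33, adjusted p = 2.47e-15), with 13 of 14 above every smolt. C035R008 changed by -3.23 (SE 0.52, adjusted p = 1.78e-07) and had a wide spread in smolts, with an SD of 2.81. C128R027 changed by -2.98 (SE 0.51, adjusted p = 5.58e-07), and by -1.40 with the leading axis score as a covariate, where 4603 probes were called. Of 16802 probes, 3387 were higher and 3902 lower in spring fish, and 1562 changed by at least 1. Hatchery smolts of the Capilano River correlated with spring fish at a median of 0.556, and the 5 other smolt groups at between -0.10 and 0.235. Without the Capilano hatchery smolts 8708 probes were called. Smolts and spring fish shared 1 slide, and with slide as a fixed block 4261 probes were called.

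**Figure D1:**
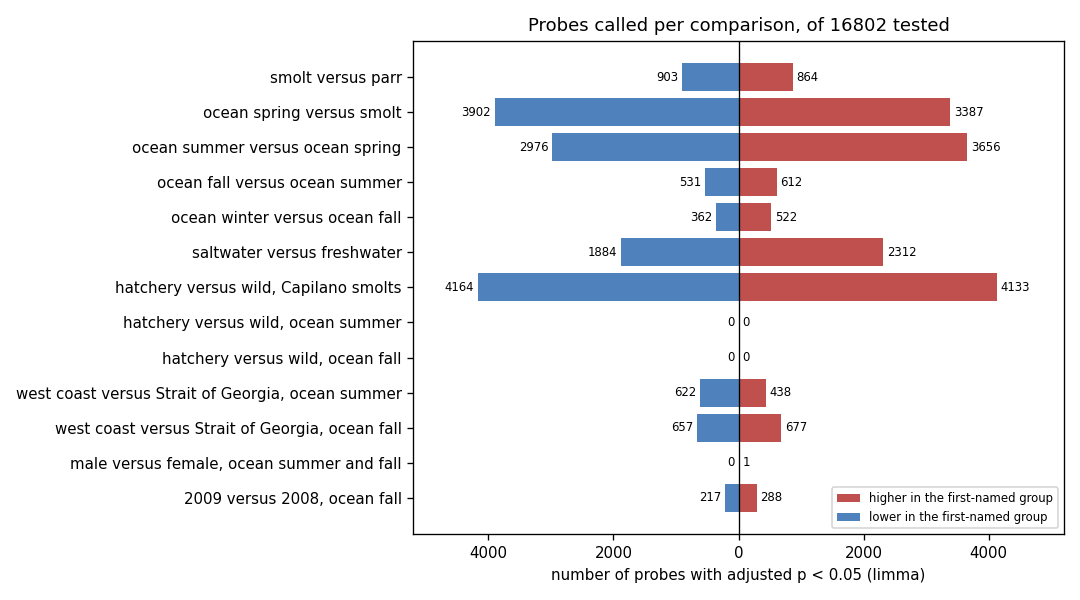
Number of probes with a limma adjusted p below 0.05 in each group comparison, with probes higher in the first-named group to the right of 0 and probes lower to the left. Hatchery versus wild Capilano smolts has 4133 higher and 4164 lower, ocean spring versus smolt 3387 higher and 3902 lower, and ocean summer versus ocean spring 3656 higher and 2976 lower, and both comparisons of origin at sea have 0 calls.

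Summer fish were then compared with spring fish. C262R149 rose from -3.52 ± 1.90 in 14 spring fish to -0.36 ± 1.45 in 66 summer fish (log2 change 3.34, SE 0.47, adjusted p = 3.23e-08). C230R165 rose by 3.09 (SE 0.46, adjusted p = 8.65e-08), and 59 of 67 summer fish lay above every spring fish. The largest falls were smaller, at -1.85 for C181R064 (SE 0.66, adjusted p = 0.0181) and -1.82 for C206R100 (SE 0.46, adjusted p = 0.00097). Of 16802 probes, 3656 were higher and 2976 lower in summer. At a change of at least 1, 859 were higher and 222 lower. All spring fish were wild and were caught in the southern Strait of Georgia in 2009. Against the 11 wild summer fish of that area and year 7 probes were called, and C262R149 (log2 change 2.42), C181R064 (-1.98) and C206R100 (-2.05) did not pass the test there. With slide as a fixed block 4164 probes were called and C181R064 stood at -3.20, and with the leading axis score as a covariate 1413 were called, without C181R064 (-1.48).

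Fall and summer fish differed less. C226R162 rose from -1.95 ± 1.74 in 67 summer fish to 0.12 ± 2.02 in 71 fall fish (log2 change 2.15, SE 0.29, adjusted p = 3.07e-09), and C134R089 by 1.90 (SE 0.27, adjusted p = 1.16e-08). C210R078 fell from 0.55 ± 1.12 in 66 to -1.42 ± 1.18 in 62 fish (log2 change -1.85, SE 0.21, adjusted p = 7.71e-12), and C220R134 changed by -1.64 (SE 0.22, adjusted p = 1.66e-09). Higher in fall were 612 probes and lower 531 of 16802, and 44 changed by at least 1. With slide as a fixed block 447 probes were called.

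Winter fish carried the largest rises among the ocean steps. C207R010 rose from -3.30 ± 1.99 in 71 fall fish to 0.34 ± 3.54 in 12 winter fish (log2 change 4.40, SE 0.56, adjusted p = 3.36e-10). C088R103 rose from -2.99 ± 1.90 to 0.63 ± 3.43 (log2 change 4.40, SE 0.52, adjusted p = 3.18e-11). These fitted changes depend on the slide block, and without it they were 3.64 and 3.62, the differences of the means. Of the 12 winter fish 7 were of the west coast, against 10 of the 71 fall fish. Both probes were higher there among wild fall fish of 2009. By the stock label most west coast winter fish were of Puget Sound, a stock of few fall fish. Stock and season were therefore partly mixed, also among west coast fish alone. The 5 winter females stood at 3.95 ± 1.94 for C207R010 and 4.02 ± 1.61 for C088R103, and the 7 winter males at -2.23 ± 1.35 and -1.80 ± 1.86. Between the winter sexes C207R010 was called (limma adjusted p = 0.0106) and C088R103 was not (limma adjusted p = 0.055). With slide as a fixed block the change from fall was 8.57 for C207R010 and 8.76 for C088R103, and for females alone 6.83 and 6.60, all past the test. The 7 winter males lay on slides that held winter fish only, so the winter fits with slide as a fixed block rest on females. For males alone it was 1.44 and 1.61, in west coast fish of 2009 it was 2.75 and 2.81, and in middle Strait fish of 2009 2.94 and 2.78, none past the test. C105R058, which had risen on entry to the sea, fell back from -0.17 ± 1.31 to -2.80 ± 0.59 (log2 change -2.71, SE 0.37, adjusted p = 8.84e-09), and C111R056 fell from 0.08 ± 0.81 to -2.53 ± 0.93 (log2 change -2.71, SE 0.33, adjusted p = 1.37e-10). Of 16802 probes, 522 were higher and 362 lower in winter, and 199 changed by at least 1. Winter and fall fish shared 1 slide, with slide as a fixed block 25 probes were called, and with the number of measured probes as a covariate 308. Without a slide block 2911 were called, in west coast fish of 2009 2402, in middle Strait fish of 2009 1418, and with quantile normalization 2049, of which 970 were higher and 1079 lower.

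Across the move from freshwater to the sea as a whole, C053R105 was the probe with the largest rise. It stood at -4.26 ± 1.35 in parr, -3.36 ± 1.93 in smolts, -0.83 ± 1.42 in spring, 0.47 ± 1.05 in summer, -0.30 ± 1.10 in fall and 1.69 ± 0.85 in winter (log2 change 3.97, SE 0.35, adjusted p = 1.1e-20). C230R165 was higher at sea by 3.27 (SE 0.38, adjusted p = 6.4e-13) but lower in spring fish, at -3.98 ± 1.26, than in smolts, at -2.92 ± 1.92. C038R110 fell stepwise from 4.18 ± 1.25 in parr to 0.14 ± 1.82 in smolts, -1.70 ± 1.32 in spring and -3.73 ± 0.96 in fall, with -2.84 ± 1.71 in winter (log2 change -5.05, SE 0.35, adjusted p = 2.93e-30). C181R064 changed by -4.12 (SE 0.55, adjusted p = 2.01e-10). Higher in saltwater were 2312 probes and lower 1884 of 16801, and 587 changed by at least 1.

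**Figure D2:**
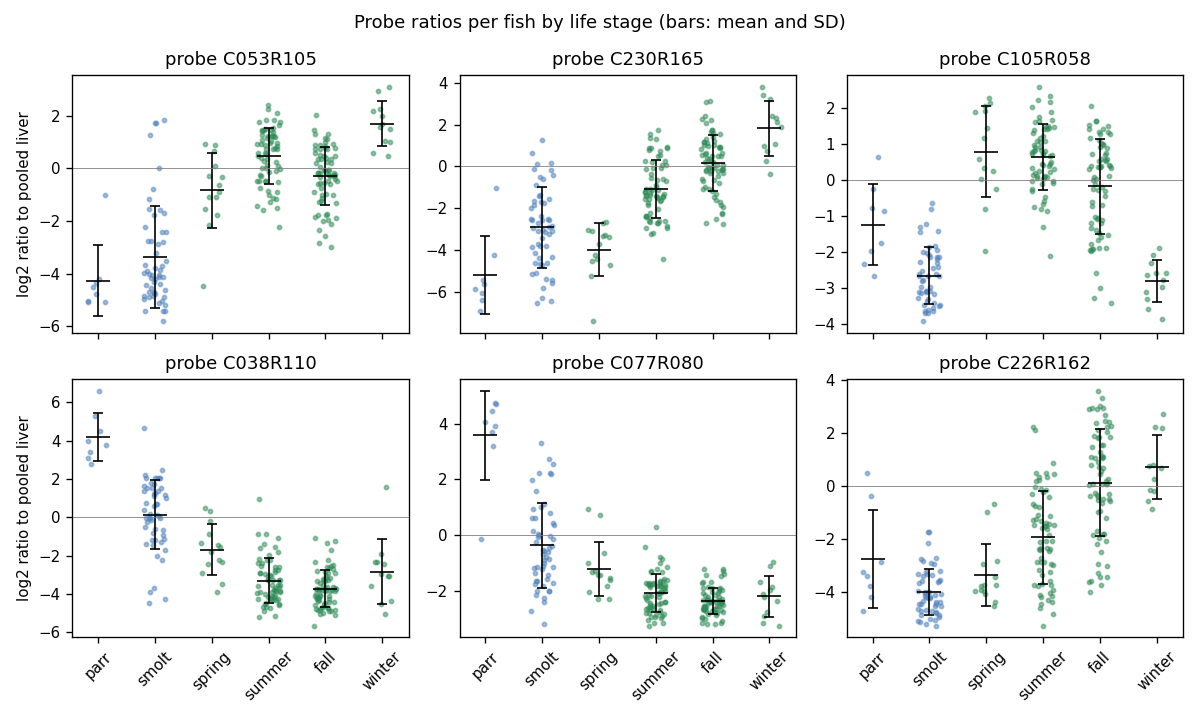
Log2 ratio to the pooled liver reference for 6 probes, with 1 point per fish (blue in freshwater, green at sea) and bars for mean and SD, by life stage. C038R110 falls from 4.18 in parr to -3.73 in fall, and C105R058 is at -2.65 in smolts, 0.80 in spring and -2.80 in winter.

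Hatchery and wild smolts were compared in the Capilano River, the river that gave both origins in the same year. C092R077 stood at 1.97 ± 1.37 in 10 hatchery and -1.37 ± 1.07 in 10 wild smolts (log2 difference 3.53, SE 0.57, adjusted p = 0.000134), and C036R006 was higher in hatchery smolts by 3.29 (SE 0.55, adjusted p = 0.000161). C192R100 stood at -5.09 ± 1.98 in hatchery and 0.48 ± 1.52 in wild smolts (log2 difference -5.69, SE 0.86, adjusted p = 0.000107), and C011R100 was lower by 5.35 on the log2 scale in hatchery smolts (log2 difference -5.35, SE 0.94, adjusted p = 0.000214). Of 16802 probes, 4133 were higher and 4164 lower in hatchery smolts, and 3819 differed by at least 1. The origins shared no slide, so slide and origin cannot be told apart here. With the score on the leading axis of variation among summer and fall fish as a covariate, 1 probe was called, and the difference was -0.38 for C192R100, -4.62 for C011R100, 2.54 for C092R077 and 2.63 for C036R006. That score nearly separates the origins and comes from the same ratios, so few calls could remain.

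**Figure D3:**
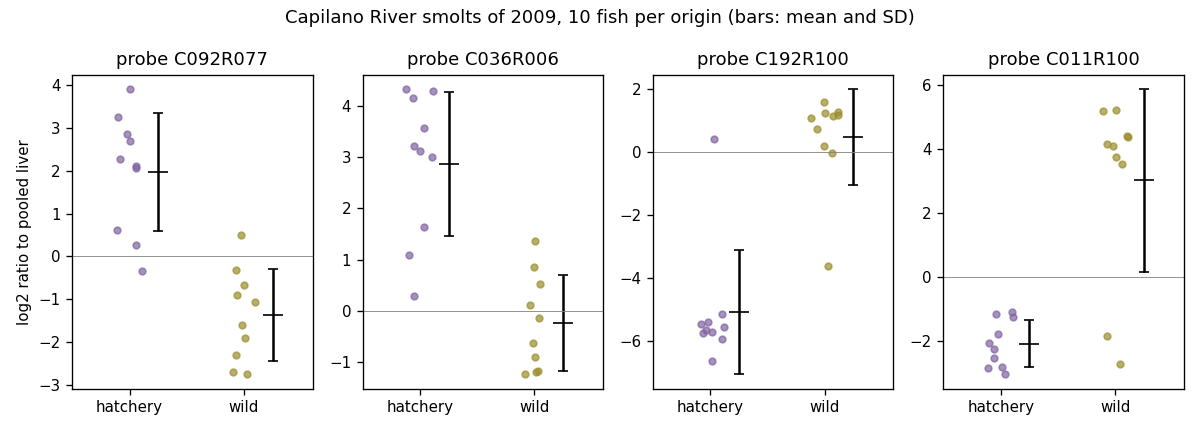
Log2 ratio to the pooled liver reference for the 4 named probes in Capilano smolts, with 1 point per fish and bars for mean and SD, 10 fish per origin. C192R100 lies near -5.09 on average in hatchery and 0.48 in wild smolts, with 1 fish of each origin far from its group.

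At sea no probe was called between origins. Among Strait of Georgia fish of 2009, 25 hatchery and 27 wild summer fish gave 0 probes with limma, with 1260 of 16802 at an unadjusted p below 0.05. The 26 hatchery and 27 wild fall fish also gave 0, with 624 at an unadjusted p below 0.05. The change of the origin effect from summer to fall gave 0 calls, with 1306 at an unadjusted p below 0.05.

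Catch area was compared among wild fish of 2009, with 9 from the west coast of Vancouver Island and 27 from the Strait of Georgia in each season. By the stock label the summer fish of the areas shared no stock (8 of the 9 west coast fish were of the Columbia), and in fall 2 of 9 west coast fish were of a stock also caught in the Strait, so stock and catch area cannot be told apart. In summer C264R049 was higher on the west coast, at 1.77 ± 1.41 against -1.40 ± 1.13 (log2 difference 3.04, SE 0.47, limma adjusted p = 0.000362), with 8 of 9 fish above every Strait fish, and C024R002 by 3.22 (limma adjusted p = 0.0247). C018R074 differed by -2.20 (limma adjusted p = 0.000324) and C131R114 by -2.10 (limma adjusted p = 0.0466). In summer 438 probes were higher and 622 lower on the west coast, and 104 and 99 with quantile normalization. In fall C207R010 was higher on the west coast by 2.97 (limma adjusted p = 0.0186) and C088R103 by 2.57 (limma adjusted p = 0.0304), while C206R127 differed by -1.98 (limma adjusted p = 0.0114) and C037R087 by -1.92 (limma adjusted p = 0.00876), with 677 probes higher and 657 lower. Quantile normalization left 432 calls in fall. With fork length as a covariate the calls were 329 in summer and 20 in fall, without C131R114 in summer (-1.81) and without any of the 4 named fall probes (C207R010 2.73, C088R103 2.40, C206R127 -1.88, C037R087 -1.21). With the leading axis score they were 181 and 2, without C024R002 (3.32) and C131R114 (-0.55) in summer and without C207R010 (3.10), C088R103 (2.83), C206R127 (-1.07) and C037R087 (-1.54) in fall, and C131R114 was also not called after quantile normalization (-1.95). The areas shared no slide in summer and 1 slide in fall, which held 1 fish of each area, a west coast male and a Strait female. With slide as a fixed block C207R010 stood at -1.74 and C088R103 at -0.79 in fall. These values compare that 1 pair of fish, so they cannot tell catch area from slide.

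Sex was tested in 69 males and 57 females of summer and fall, with season as a covariate. The single probe called of 16802 was C108R116, higher in males at 0.17 ± 1.42 in 32 summer fish and 0.67 ± 1.55 in 35 fall fish, against -1.28 ± 1.00 in 23 summer and -1.39 ± 0.33 in 31 fall females (log2 difference 1.80, SE 0.21, adjusted p = 1.07e-09), and it was also the single call with slide as a fixed block. Males spread from -2.12 to 3.62, and females lay below 0 in both seasons except for 1 summer female. At an unadjusted p below 0.05 there were 518 probes. The change of the sex effect between the seasons gave 0 calls with limma, with 1012 at an unadjusted p below 0.05.

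**Figure D4:**
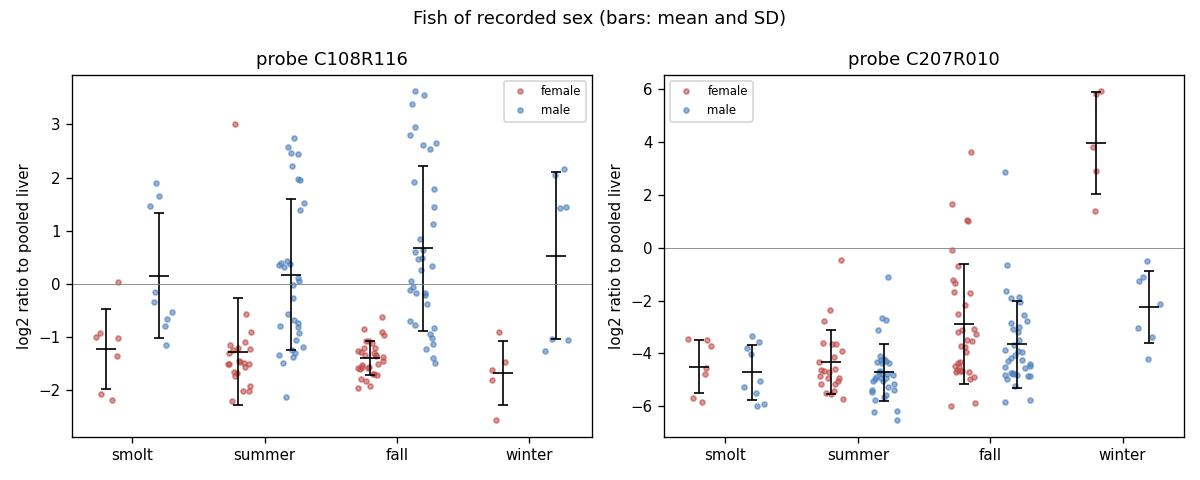
Log2 ratio to the pooled liver reference for C108R116 and C207R010 in fish of recorded sex, with 1 point per fish (red for females, blue for males) and bars for mean and SD. In C207R010 the 5 winter females lie between 1.39 and 5.90 and the 7 winter males between -4.22 and -0.51.

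Wild fall fish of the Strait of Georgia differed between 27 fish of 2009 and 8 of 2008 in 505 probes, 288 higher and 217 lower in 2009. C055R074 was higher in 2009, at 0.13 ± 0.61 against -2.11 ± 0.71 (log2 difference 2.27, limma adjusted p = 0.000832), and all 23 measured fish of 2009 lay above all 6 of 2008. C215R152 was higher by 2.20 (limma adjusted p = 0.0171), C083R026 differed by -2.04 (limma adjusted p = 0.0228) and C013R010 by -1.64 (limma adjusted p = 0.00106). The years shared no slide, so slide and year cannot be told apart here. By the stock label 9 of the 27 fish of 2009 were of ECVI and 8 of S_Main. No fish of 2008 carried either label, so stock and year were partly mixed too. Quantile normalization gave 256 calls, and with the leading axis score as a covariate limma called 0 (1529 at an unadjusted p below 0.05), with differences of 2.21 for C055R074, 1.64 for C215R152, -2.78 for C083R026 and -1.33 for C013R010. Fork length was tested with the catch areas pooled. In fall, west coast females averaged 30.8 cm and males 29 cm, against 24.2 and 24.8 cm in the Strait. Slopes were not fitted within an area, so length and catch area were partly mixed. With fork length, 60 probes rose and 56 fell in summer, and 361 rose and 342 fell in fall. After quantile normalization 40 were called in summer, 37.5% of them rising, and 178 in fall, 60.7% of them rising. The largest slopes among called probes in summer were those of C127R085 (0.32 per cm, adjusted p = 0.04), C042R127 (0.25 per cm), C179R159 (-0.24 per cm) and C146R037 (-0.23 per cm). In fall the slopes were 0.43 per cm for C028R039 (adjusted p = 0.000297), 0.30 for C239R110, -0.21 for C126R142 and -0.19 for C112R032. C127R085 was not called without a slide block (0.29 per cm), with quantile normalization (0.30) or with the leading axis score as a covariate (0.15). With that score most of the other named slopes were not called either. With slide as a fixed block 0 probes were called in either season with limma, with 1724 in summer and 2281 in fall at an unadjusted p below 0.05. The slopes there were 0.39 for C127R085, 0.23 for C042R127, -0.28 for C179R159, -0.29 for C146R037, 0.40 for C028R039, 0.21 for C239R110, -0.16 for C126R142 and -0.19 for C112R032.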

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

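Tests chosen only after the result was seen were the comparison of the origin effect between Capilano smolts and summer fish, the winter test of sex, the tests of measured probes and hatchery rearing for Capilano smolts, those of slide, catch area, winter size and size within the Strait for C207R010, and those on smolts 23 and 26, and the leading axis itself was chosen after the data were seen. Chance marks about 1 in 20 groups of values as holding a fish far from the others, and 8 of 39 groups tested held such a fish.

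Hatchery smolts of the Capilano River scored 1.53 ± 0.621 on the leading axis and spring fish 1.30 ± 0.985, against -0.598 ± 0.747 for wild Capilano smolts. Exchange with ocean fish is argued against by the probes called between saltwater and freshwater without either set. On these, 1 of the 10 hatchery smolts lay on the saltwater side (mislabelled sample), against 9 of 14 spring fish. Of the other freshwater fish 15 of 52 also lay there. Spring fish averaged -0.218 ± 0.304, near the midpoint of -0.308 between freshwater and saltwater means, so the side alone marks spring fish poorly. Hatchery smolts averaged -0.734 ± 0.206. The number of measured probes as a covariate left the axis gap between the origins at 2.14 (95% interval 1.49 to 2.79). Slide stays open, because on the 4 slides with other fish 6 hatchery smolts scored 1.26 above 10 others with an interval of 0.12 to 2.39. Hatchery rearing also stays open, with a difference between origins of 0.683 (0.00905 to 1.36) in smolts of the other rivers and, at sea, of -0.53 (-1.01 to -0.0534) in summer and 0.24 (-0.244 to 0.724) in fall. Each of the other rivers gave a single origin, and the Chilliwack smolts were of 2008, so river and year cannot be told apart from rearing there. Mean scores were -0.00866 in Chilliwack and -0.816 in Salmon wild smolts, and 0.444 in Chehalis and 0.166 in Puntledge hatchery smolts. What the axis measures in the liver was not tested, and a shared state of these smolts and newly arrived ocean fish is a hypothesis that may be checked with named genes.

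C207R010 stood at 3.95 ± 1.94 in 5 winter females (33.4 ± 2.34 cm) and -2.23 ± 1.35 in 7 winter males (35.6 ± 1.58 cm). Of 16802 probes tested between the winter sexes with limma, 3 were called, all higher in females: C207R010 (log2 difference 5.93, limma adjusted p = 0.0106), C065R146 (5.78, limma adjusted p = 0.0106) and C154R149 (2.03, limma adjusted p = 0.00839), while C088R103 was not called (5.60, limma adjusted p = 0.055) and the change of the sex effect from fall to winter gave 0 calls (758 at an unadjusted p below 0.05, limma adjusted p = 0.229 for C207R010 and C088R103). Catch area and fork length as covariates left the winter difference between the sexes at 6.28 (95% interval 3.86 to 8.69) and 6.84 (4.40 to 9.27). With slide and stage as terms it was 3.89 (1.03 to 6.74). That value rests on the 1 slide that held both winter sexes (1 female, 3 males), and its interval takes the spread from all fish. The value of 7.98 (5.93 to 10.0) against 10 other fish of the females' slides mixed stage with sex, so slide stays open. In 34 fall females C207R010 was correlated with fork length (Pearson r = 0.552, permutation p = 9e-04; Spearman rho = 0.522, permutation p = 0.00185; r = 0.547 without the 2 fish whose length lay farthest from the median), but 6 of them were longer west coast fish, and in the 28 of the Strait r was 0.142 (95% interval -0.244 to 0.489, permutation p = 0.47; rho = 0.21, permutation p = 0.28; r = 0.0999 without 2 fish). In the 6 west coast females r was -0.542 (95% interval -0.94 to 0.481). Over 36 fall males of both areas r was 0.353 (permutation p = 0.0386) and rho 0.316 (permutation p = 0.0605). Size of the fish and catch area in fall therefore cannot be told apart, a reading set after the pooled correlation had met its prediction, and a biological difference between the sexes in winter remains a hypothesis.

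Smolt 23, a hatchery fish of the Capilano River, scored -0.222 on the axis (others 1.53 to 1.84) and 0.41 for C192R100 (others -6.65 to -5.15). Smolt 26, a wild fish of that river, scored 1.47 (others -1.18 to -0.553) and -3.61 for C192R100 (others -0.03 to 1.59). Both fish, 2 of 2, correlated more with the other origin (0.366 against 0.290, and 0.663 against 0.0173), as swapped labels would give, and of the other 18 smolts 0 did, while with the axis removed 0 of the 2 (0.399 against 0.501, and 0.406 against 0.450) and 2 of the other 18 did. Other named probes ran with the labels, since smolt 23 stood at 2.07 for C092R077, 3.21 for C036R006 and -1.26 for C011R100 (hatchery means 1.97, 2.88 and -2.09) and smolt 26 at 4.17 for C011R100 (wild mean 3.02), while smolt 26 stood above the other wild smolts for C092R077 (0.50) and C036R006 (1.36). Position on the leading axis alone may account for the pattern, and a swap stays open because the origins shared no slide, a reading set after the result, with 10091 probes called between the origins without both fish.

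In parr, replicate 5 stood at -0.13 for C077R080 (others 3.18 to 4.76). Replicate 1 stood at -1.03 for C053R105 (others -5.07 to -4.22) and -1.03 for C230R165 (others -6.92 to -4.25). A fall fish of 2008, replicate 5, stood at -0.72 for C215R152 (others -3.65 to -2.50).

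The effect of catch area differed between fall and summer for C048R152, by -1.33 (limma adjusted p = 0.0102). In summer 9 west coast fish stood at 0.23 ± 0.45 and 27 Strait fish at -0.47 ± 0.32, and in fall at -1.07 ± 0.28 and -0.47 ± 0.51. The fitted effect of origin differed between Capilano smolts and summer fish in 8409 probes (4236 with a higher and 4173 with a lower effect in smolts), but the Capilano origins shared no slide, so slide and origin cannot be told apart in this difference.

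Splits of the same fish into groups of the same sizes, 100 per comparison and the real split included, were fitted without the slide block and did not keep fish of a slide together. They bear on a chance assignment of single fish and not of whole slides, so chance is excluded below only for single fish. On that basis chance can be excluded for smolt versus parr (1 split as large; real 3757, highest other 2660), ocean spring versus smolt (1; 7914, 3525), ocean summer versus ocean spring (1; 7288, 5), ocean fall versus ocean summer (1; 1524, 1), ocean winter versus ocean fall (1; 2910, 39), saltwater versus freshwater (1; 6232, 918), the Capilano origins (1; 9642, 1), catch area in summer (1; 1928, 199) and catch area in fall (1; 2033, 67). Few splits were as large for catch year (1; 1819, 1641) and sex (3; 1, 322). Another split came near the real count for catch year and lay far above it for sex, so the splits do not exclude chance for these counts. The sex call was the single probe C108R116 (limma adjusted p = 1.07e-09). That value argues against chance for this probe, on which a count of calls does not bear. Males also had the higher mean in smolts and winter fish, which did not enter the test. Smolt versus parr, the Capilano origins, catch area in summer and catch year had no slide with both groups. Ocean spring versus smolt, ocean winter versus ocean fall and catch area in fall shared 1 slide, with 1 fish of each group on it. Chance between slides stays open for all of these, and the splits did not test it for any comparison. For the seasonal change of the catch area effect (2; 51, 2558) 1 probe was called with the slide block, and other splits called many more than the real one, so chance is not taken as excluded. With a real count of 0 every split calls as many, so the splits decide nothing and chance cannot be excluded for origin in summer (100; 0, 5), origin in fall (100; 0, 1), and the seasonal changes of the origin effect (100; 0, 3263) and of the sex effect (100; 0, 45), all fitted with limma's model, where 1260, 624, 1306 and 1012 probes had an unadjusted p below 0.05 with the slide block. The highest other splits for sex (322) and for the seasonal changes of the catch area effect (2558) and of the origin effect (3263) lay far above the real counts. A structure of the samples may give this, which slides alone could also do, but none was tested or identified.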

How the results depend on the processing

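Alternatives chosen only after the result was seen were the leading axis score, the number of measured probes, the slide as a fixed block within stages, the fits of each sex in winter and those without single fish. No paired analysis was possible because replicate numbers only name fish. Of the named probes' values under the alternatives, 334 kept direction and call, 49 lost the call and 2 reversed. Alternatives that changed only the probe set or the variance model could not change a direction. The named probes were also chosen as the largest changes, so the 334 do not measure stability. Median-centring of arrays kept the counts of the 6 stage comparisons within 1.5 times. Planned and not run were the processed table against the series matrix, slide as a fixed block for parr and for saltwater versus freshwater, the camera test, the gene lists and the IGF1 test. Empty cells limit what was tested to 16802 probes, and signal over background was not used here.

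Without a slide block the calls were 3757 for smolt versus parr, 2911 for winter versus fall, 1928 and 2033 for west coast versus Strait in summer and fall, 1819 for 2009 versus 2008 and 1476 for fork length in fall. With slide as a fixed block they were 4261 for spring versus smolt, 4164 for summer versus spring, 447 for fall versus summer and 25 for winter versus fall. The winter males lay on slides of winter fish only and did not enter that last difference. With slide as a fixed block limma called 0 for fork length in summer (1724 at an unadjusted p below 0.05) and in fall (2281). For west coast versus Strait in fall C207R010 reversed to -1.74 and C088R103 to -0.79. The slide shared there held 1 fish of each area, so these values compare 1 pair of fish. Quantile normalization gave 855 for smolt versus parr, 1726 for fall versus summer, 2049 for winter versus fall, 203 and 432 for west coast versus Strait in summer and fall, 256 for 2009 versus 2008, and 40 and 178 for fork length in summer and fall. It moved the share of higher calls from 59.0% to 47.3% for winter versus fall and from 51.7% to 37.5% for fork length in summer. The cause was not tested.

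With the leading axis score as a covariate the calls were 2889 for smolt versus parr, 4603 for spring versus smolt, 1413 for summer versus spring, 2046 for fall versus summer, 552 for winter versus fall, 1 for the Capilano origins, 181 and 2 for west coast versus Strait in summer and fall, 0 for 2009 versus 2008 (limma, 1529 at an unadjusted p below 0.05), and 1 each for fork length in summer and fall. With the number of measured probes as a covariate winter versus fall gave 308. With fork length as a covariate west coast versus Strait gave 329 in summer and 20 in fall. The cause was not tested.

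Fewer probes tested lowered the counts by construction. The 7169 probes measured on every array gave 930 for smolt versus parr, 3589 for spring versus smolt, 3409 for summer versus spring, 522 for fall versus summer, 395 for winter versus fall and 1946 for saltwater versus freshwater. The more variable probes, 8401 tested, gave 4373 for spring versus smolt, 4250 for summer versus spring, 558 for winter versus fall and 2430 for saltwater versus freshwater.

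Fewer fish entered the following. With 8 fish per group the median of 20 draws was 680 for smolt versus parr, 2004.5 for spring versus smolt, 1185.5 for summer versus spring, 0 for fall versus summer (limma, range 0 to 57), 33.5 for winter versus fall and 2047 for saltwater versus freshwater. The 2008 Chilliwack smolts gave 621 against parr. Wild fish of 2009 of the southern Strait gave 7 for summer versus spring. Winter versus fall gave 2402 in west coast fish and 1418 in middle Strait fish of 2009, more than with all fish, for which the cause was not tested, and 185 in females and 231 in males.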

Other observations

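The splits of whole slides, the listing of probes by stage and the leading axis were chosen only after the result was seen, and the other tests on the spring fish before. Across the 8 pairs of an ocean stage with parr or smolts, 59 probes were called higher in every pair and 95 lower in every pair. C053R105 was among the higher, and C038R110 and C181R064 among the lower. Of 26765 probes left out of the fits for empty cells, C184R085 was measured on 100% of parr and on 5.6% of smolts, 7.1% of spring, 4.5% of summer, 4.2% of fall and 0% of winter fish.

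C108R116, the probe that differed by sex at sea, stood at -1.22 ± 0.75 in 7 female and 0.16 ± 1.18 in 9 male smolts. In winter it stood at -1.67 ± 0.60 in 5 females and 0.54 ± 1.57 in 7 males. Spread among males was wide in each stage, and sex was recorded in 17 of the 54 smolts.

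For many probes the fitted changes from smolt to spring and from spring to summer had opposite signs. Called in both steps were 2108 probes higher and then lower, 2441 lower and then higher, 20 higher in both and 17 lower in both. Both steps share the spring fish, which alone gives a negative correlation across probes: it was -0.761 as observed and -0.810 with stage means removed and stages shuffled between fish. With different spring fish in each step (7 and 7, 100 splits) the median correlation was -0.612 (splits -0.709 to -0.406), and with whole slides in each part (5 to 9 fish) and no smolt or summer fish of those slides -0.556 (-0.699 to -0.349), which argues against the shared spring fish and their slides as the whole of it. With the axis score as a covariate these were -0.288 (-0.402 to -0.101) and -0.256 (-0.412 to -0.00388), so the leading axis may account for part of it, and the summer step gave 1413 calls with the axis score and 7 in wild 2009 fish of the southern Strait, so a change back by summer remains a hypothesis.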
